A study of Mus musculus with 6 samples.

How the data were processed

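E2A was mapped by ChIP-seq in proliferating neural stem cells from embryonic day 12.5 mouse embryos: 3 wild-type libraries, 1 from E12 knockout cells, 1 from E47 knockout cells and 1 input library. Per the labels' protocols, cells were fixed with 1.5 mM EGS for 20 min and then 1% formaldehyde for 10 min, chromatin was precipitated with 1.5 µg of an antibody against E2A, and libraries were made from 2 ng of ChIP DNA selected for inserts of 360 to 600 bp. Groups and replicate numbers came from the labels. The input library entered no comparison, and its data were not analysed here.

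Per the submitters' processing notes, BWA 0.7.13, Picard 1.119 and MACS2 2.1.0 were used with the mm9 mouse genome; their settings and order are not given in the sources used here. The deposited names carry a false discovery rate label that differs between wt replicate 1 and the other 4 lists. The lowest −log10 q in wt replicate 1 was 2.07, the thresholds of the other lists could not be checked, and a different threshold would change list lengths, overlaps and the counts of missing regions. The lists were deposited per library, not for pooled samples. Each gives a peak's start and end, the annotated feature, the nearest gene and the signed distance to its transcription start site, per the file headers. Only the deposited table of wt replicate 1 also holds, per peak, the −log10 p and −log10 q at the summit, a fold enrichment (a ratio of ChIP to the caller's background) and the pileup signal (coverage height), as the authors' peak caller gave them. These scores are the authors' and were used only to describe or rank peaks within that list, where −log10 q ran from 2.07 to 534, fold enrichment from 1.69 to 106 and pileup from 11 to 513. A fold given for a region is that of the wt replicate 1 peak. The annotation of wt replicate 1 separates promoters within 1 kb from those at 1 to 2 kb and measures distance to another edge of the peak than the other 4 tables do, so its distances can differ by a peak width. Its list was also made differently in other respects: it has no peak under 280 bp, while the other lists have 12 to 52 peaks under 150 bp, every one of them with an edge at a multiple of 100 bp.

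Median peak widths were 432.5, 420, 549, 616 and 550 bp in wt replicates 1 to 3, E12KO and E47KO. Positions given for a region are those of the merged region, and those of a gene list member are those of the wt replicate 1 peak. Peaks shared by lists had to overlap by at least 1 bp. The wt peaks were merged where they overlapped, and a merged region in at least 2 of the 3 lists was a wt consensus region. The share of these regions with a peak in a knockout was given with a 95% Wilson interval, which covers counting error only. For the spread between replicates, regions shared by 2 wt lists were looked up in the held-out wt list and in each knockout. Random overlap came from 100 placements of each list's peaks on the same chromosomes. No test between genotypes was made, since each knockout has 1 library.

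A target gene was the gene annotated to a peak within 10 kb of its start site. The 22 gene lists (458 entries, 6 genes in more than 1 list) were compared with the other protein-coding genes of a RefSeq gene table (GRCm38, used for names and gene class only; 21900 protein-coding genes) by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists, at 0.05. Of 12140 gene identifiers in the peak lists, 12078 were in that table. The lists were E proteins and Id factors, proneural bHLH factors, the Notch, Wnt, Sonic hedgehog, and BMP and TGF-β pathways, FGF and EGF signalling, CDK inhibitors and cell cycle exit, cell cycle drivers, neural stem cell, astrocyte, microglia, endothelial, and mural and fibroblast markers, projection neuron and interneuron differentiation, oligodendrocyte lineage, axon guidance, lymphoid E2A targets, skeletal muscle, housekeeping and ribosomal protein genes. For single libraries, list counts were set among 10000 random gene lists of the same size.

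The groups, gene lists, comparisons and the rule for named genes were fixed before the data were examined. Named were Tcf3 and Cdkn1c in every library; the 10 strongest regions in all 3 wt lists; of the regions in all 3 wt lists, the 10 strongest missing in E12KO only, in E47KO only and in both; the 10 highest regions in both knockouts and no wt list; and up to 4 bound members per gene list, those with the strongest consensus region, with any member missing from both knockouts. Values of a few genes that the rule names are not reported. The plan was to rank regions over the scores of all lists. Since 4 lists have none, strength means the −log10 q of wt replicate 1, the 5 strength bins hold that list's peaks, and regions in both knockouts and no wt list were ranked by width. Width is a weak stand-in for strength: across wt replicate 1 peaks its rank correlation with −log10 q was 0.683, but the width of the overlapping peak in the other 4 lists correlated with that score at only 0.105 to 0.213 (across peaks, which are not replicates). E-box motifs were planned and not counted, because no mm9 genome sequence was used here.

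Alternatives were peak centres (summits in wt replicate 1) within 200 bp, overlap of at least 0.5 of the shorter peak, autosomes and X only, regions in all 3 or in any wt list, leaving out each wt replicate, and start site distances of 5 kb, 50 kb or any. Chosen after seeing the data were lists trimmed by width to the length of the shortest (6814 peaks), the wider 0.5 of each list, E12KO trimmed to the length of E47KO, a background of genes that any list names, and random lists matched on gene length in 10 bins within it, with the exact distribution of their counts. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. They were tested on simulated data: the overlap search gave the same pairs as a direct comparison for all 10004 overlapping pairs, the region counts for 12000 simulated regions were recovered with 0 differences, and of 500 simulated lists of 20 genes in which 60% of genes were expected to be bound, 95.8% passed the Fisher test, against 1.41% of 1700 unseeded lists. Bound genes and unseeded lists were drawn evenly over all genes in the simulation. That rate therefore leaves out effects of gene length or of a gene's surroundings on the real lists.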

Results

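E2A is the product of Tcf3, a basic helix-loop-helix (bHLH) gene whose alternative splicing gives the E12 and E47 proteins. Both proteins bind E-box DNA as dimers with other bHLH factors and are held off DNA by the Id proteins. The series mapped E2A binding by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural stem cells grown from E12.5 mouse embryos (strain C57BL/6J). The cells were kept proliferating with FGF-2 and EGF at 20 ng/ml each. Of the 6 samples, 3 were wild type (wt replicates 1, 2 and 3), 1 lacked E12 (E12KO), 1 lacked E47 (E47KO) and 1 was input DNA. A peak list was analysed for 5 of them, with 6814, 12772 and 24194 peaks in wt replicates 1, 2 and 3, 25229 in E12KO and 22176 in E47KO. The wt lists averaged 14593 ± 8832 peaks (SD, n = 3), and the longest of them held 3.55 times as many peaks as the shortest. The E47KO count lay within the range of the wt counts and the E12KO count just above it. Read depth is unknown, because the lists give no read totals. With 1 library per knockout, no test between genotypes was made and no value for a knockout has a replicate error. The labels do not say whether the wt samples came from separate embryos or cultures.

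The gene that encodes E2A was itself bound in the longer lists. A peak covered the Tcf3 promoter on chromosome 10 (mm9) from 79895814 to 79897054 in wt replicate 3, from 79896025 to 79896882 in E12KO and from 79896046 to 79897042 in E47KO, while wt replicates 1 and 2 had no peak annotated to Tcf3. Another, intergenic peak 10747 bp upstream of the Tcf3 start site was listed in wt replicate 3 and, at 10734 bp, in E12KO, and not in E47KO. Peak positions say nothing about whether the E12-specific or E47-specific exon was lost in the knockout cells, so the genotype labels could not be checked from these lists.

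Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, carried distal peaks in every library, with none within 10 kb of its start site. The gene spans 150644244 to 150646955 on the minus strand of chromosome 7. One intergenic peak lay about 22.5 kb downstream of the start site, at 150623712 to 150624423 in E47KO and 150623660 to 150624388 in E12KO, and it was present in all 3 wt lists (for wt replicate 3, 150623722 to 150624397). Another, about 32 kb downstream, ran from 150614295 to 150614838 in E47KO and from 150614299 to 150614795 in E12KO and was likewise in all 3 wt lists. In wt replicate 1 the authors' fold enrichment was 7.27 at the nearer site and 8.19 at the farther one. A peak inside the last intron of the potassium channel gene Kcnq1, 59.2 kb from the Cdkn1c start site in both wt replicate 3 and E12KO, was listed in wt replicates 1 and 3 and in E12KO but not in wt replicate 2 or E47KO, so 1 of the 3 wt lists lacked it as E47KO did. E12KO alone had another peak, from 150619308 to 150619602.

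**Figure D1:**
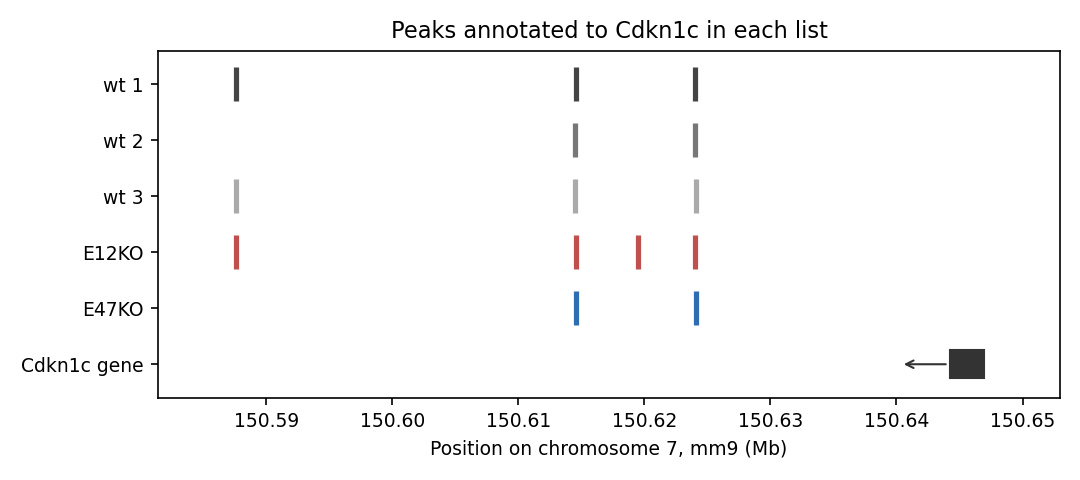
Peaks annotated to Cdkn1c in each list. The x axis is the position on chromosome 7 in mm9 (Mb), each vertical tick marks the middle of 1 peak, the box is the gene and the arrow its direction of transcription. The peaks nearest to the gene and about 32 kb from its start stand in all 5 lists, and the leftmost peak is absent from wt replicate 2 and E47KO.

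The wt lists together gave 26817 merged regions, of which 12322 were found in at least 2 lists (wt consensus regions) and 4228 in all 3. Overlap followed list length. Of the peaks of wt replicate 1, 63.4% were shared with wt replicate 2 and 82.7% with wt replicate 3, and of the peaks of wt replicate 2, 88.2% were shared with wt replicate 3. In the other direction 22.7% of the peaks of wt replicate 3 were found in wt replicate 1 and 45.6% in wt replicate 2. Consensus regions numbered 11013 without wt replicate 1, 5491 without wt replicate 2 and 4263 without wt replicate 3. A region then had to be in both remaining lists, so lower counts follow from that rule. The 6 directed shares averaged 56.0% ± 26.5 (SD), and random placement of the same peaks on the same chromosomes gave at most 1.15% for any of these pairs on average.

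Only wt replicate 1 carries a score per peak, so strength was ranked in that list. The strongest region shared by all 3 wt lists lay on chromosome 17 from 25804218 to 25806568, 49047 bp upstream of Gng13, with a fold enrichment of 106. It was followed by a region on chromosome 17 (9967688 to 9970163) in exon 1 of a transcript lying 107278 bp upstream of Pabpc6, at 104-fold, and by the promoter of the ubiquitin-conjugating enzyme gene Ube2r2 on chromosome 4 (41082079 to 41083751), at 96.1-fold. The other 7 of the 10 strongest were annotated to Brd7 (74.4-fold), which encodes a bromodomain protein of a SWI/SNF complex, Jmjd1c (71.9-fold), the mitochondrial ornithine carrier Slc25a15 (79.8-fold, at its promoter), Etv5 (74.3-fold), Rplp1, Mcur1 and Eipr1. The region annotated to Etv5, an ETS factor downstream of FGF signalling, lay 70138 bp upstream of its start site in intron 4 of Dgkg (chromosome 16, 22508611 to 22510245). All 10 had a peak in both knockouts.

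Genes of the Notch pathway, which keeps neural progenitors undifferentiated, were bound far more often than other genes. Within 10 kb of the start site, 18 of 26 had a wt consensus region, against 16.6% of other protein-coding genes (odds ratio 11.3, two-sided Fisher's exact test, Benjamini-Hochberg adjusted exact p = 8.3e-08 over 22 lists). The strongest sites were the promoter of the effector Hes5 (chromosome 4, 154334317 to 154335521, 58.8-fold), the last intron of the coactivator gene Maml3 (33.1-fold), a site 1316 bp upstream of Hes6 (31.5-fold) and one 1552 bp upstream of the ligand gene Dll1 (26.6-fold). The Maml3 site was in wt replicates 1 and 3 and in E47KO but in neither wt replicate 2 nor E12KO, while the other 3 were in all 5 lists. Numb, named after its values were seen, was the only one of the 18 with no peak within 10 kb in E12KO, and all 18 had one in E47KO. The odds ratio was 19.2 without wt replicate 2, 21.2 without wt replicate 3 and 6.42 (adjusted exact p = 4.1e-04) against the genes that any list names.

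Neural stem cell markers were also bound more often, 15 of 25 (odds ratio 7.53, Fisher's exact test, adjusted exact p = 1.4e-05), led by Sox1 (22.01-fold, 6064 bp downstream of its start), the RNA-binding protein gene Msi1 (12.1-fold, in intron 6), the intermediate filament gene Nes (9.22-fold, in exon 3) and the promoter of Fabp7 (7.41-fold). Astrocyte markers followed with 11 of 18 (odds ratio 7.88, adjusted exact p = 2.0e-04). Their strongest members were the nuclear factor I genes, transcription factors that stem cells also express: the promoters of Nfix (27.4-fold) and Nfia (17.1-fold), and a site 2757 bp upstream of Nfib (11.6-fold). Aldh1l1 had a site 9501 bp upstream at 9.44-fold. The odds ratio of stem cell markers was 12.1 without wt replicate 3, and that of astrocyte markers 11.96 without wt replicate 2. Against the genes that any list names they were 3.56 (adjusted exact p = 0.035) and 4.70 (adjusted exact p = 0.036). All members of these lists with a wt consensus region had a peak within 10 kb in both knockouts. These 2 lists and the Notch pathway were the only ones of the 11 past the threshold to remain so under all 10 alternative settings.

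E proteins and their Id antagonists were bound at 5 of 7 genes (odds ratio 12.52, 95% interval 2.05 to 131.5, Fisher's exact test, adjusted exact p = 0.0073). Id1 had a site 1409 bp upstream of its start on chromosome 2 (152560601 to 152561267) at 45.2-fold, Id2 one 3226 bp upstream at 35.8-fold, Id3 one 3578 bp upstream at 34.7-fold and Tcf12 one 1756 bp upstream at 9.69-fold, all in all 5 lists. The other bound gene, named after its values were seen, was Tcf4 at 8.96-fold. Tcf3 and Id4 had no wt consensus region by this rule, but both had peaks within 10 kb in single lists. Those of Id4 were in wt replicates 2 and 3 and both knockouts, and those of Tcf3 in wt replicate 3 and both knockouts. Without wt replicate 2 the odds ratio was 29.8 and without wt replicate 3 it was 45.1. The call ended against the genes that any list names (5.33, adjusted exact p = 0.14) and against random lists matched on gene length (5 against 2.26, adjusted exact p = 0.34). By contrast, only 2 of 15 proneural bHLH genes, the usual dimer partners of E proteins in neurogenesis, had one (odds ratio 0.769, adjusted exact p = 1.00), among them Insm1, 4799 bp upstream of its start (10.7-fold). That odds ratio turned to 1.83 without wt replicate 2 (adjusted exact p = 0.45) and 2.77 without wt replicate 3 (adjusted exact p = 0.26).

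CDK inhibitor and cell cycle exit genes had a wt consensus region at 8 of 19 (odds ratio 3.64, Fisher's exact test, adjusted exact p = 0.019), with Gadd45g (18.9-fold, 1033 bp upstream), the promoters of Gas1 (7.42-fold) and Cdkn2b (6.16-fold), and Cdkn1b, which encodes p27 (4.22-fold, 8396 bp downstream). Cell cycle drivers, their opponents, were bound at 8 of 22 (odds ratio 2.86, Fisher's exact test, adjusted exact p = 0.042), and the difference between these lists was not tested. Their strongest members were E2f1 (17.8-fold), E2f2 (7.42-fold), Ccnd2 (6.66-fold) and E2f3 (5.05-fold). The strongest E2f2 site, in intron 1, was in wt replicates 1 and 3 and in neither knockout. Without wt replicate 2 neither list passed (Fisher's exact test, adjusted exact p = 0.10 and 0.15), nor without wt replicate 3 (adjusted exact p = 0.13 and 0.16), nor against the genes that any list names. Leaving out a replicate requires a region to be in both remaining lists. Fewer regions then remain, so a call can end without a lower odds ratio.

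Neuronal and signalling lists were bound to differing degrees. Projection neuron genes had 14 of 28 (odds ratio 5.02, Fisher's exact test, adjusted exact p = 2.6e-04), led by the corepressor gene Tle4 (21.7-fold), the promoter of Pou3f2, which encodes BRN2 (25.9-fold), Map2 (11.5-fold) and Foxp1 (10.7-fold). Their odds ratio was 8.58 without wt replicate 3, and the call ended against the genes that any list names (2.30, adjusted exact p = 0.14) and against random lists matched on gene length (14 against 9.49, adjusted exact p = 0.40). The FGF and EGF, Sonic hedgehog, and BMP and TGF-β calls below also ended under both. FGF and EGF signalling had 12 of 25 (odds ratio 4.63, adjusted exact p = 0.0012), with Fgfr1, Spry2, Etv5 and Spred2 between 7.12-fold and 9.97-fold. Sonic hedgehog had 7 of 15 (odds ratio 4.38, adjusted exact p = 0.018), with Gli2 at 15.5-fold, Ptch1 at 8.32-fold, Gas1 at 7.42-fold and Cdon at 6.76-fold. BMP and TGF-β had 12 of 31 (odds ratio 3.17, adjusted exact p = 0.0088), with the promoter of Skil at 23.9-fold, Bmp7 at 18.4-fold, the promoter of the BMP antagonist gene Chrd at 9.55-fold and Bmpr1a at 8.69-fold. Leaving out wt replicate 1 ended the BMP and TGF-β call (odds ratio 1.72, Fisher's exact test, adjusted exact p = 0.32), and its odds ratio was 5.69 without wt replicate 2. Leaving out wt replicate 2 ended that of Sonic hedgehog (4.33, 0.054). Leaving out wt replicate 3 ended those of FGF and EGF signalling (3.43, 0.091), Sonic hedgehog (4.503, 0.091) and BMP and TGF-β (3.47, 0.060). Fewer regions remained there, and the odds ratios of Sonic hedgehog and of BMP and TGF-β were not lower than with all 3 wt lists.

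Several lists did not pass the test. Wnt pathway genes had 10 of 31 (odds ratio 2.39, Fisher's exact test, adjusted exact p = 0.052), with Wnt5a at 23.4-fold, Fzd9 at 18.1-fold, Nkd1 at 9.98-fold and Apc at 6.28-fold. Axon guidance genes had 10 of 32 (2.28, adjusted exact p = 0.082), with Slit1 at 22.1-fold, Plxna2 at 20.7-fold, Sema6d at 8.73-fold and Plxna4 at 7.84-fold. Oligodendrocyte lineage genes had 6 of 16 (3.004, adjusted exact p = 0.064), with Zfp488 at 34.5-fold, the NG2 gene Cspg4 at 16.9-fold, and sites beside Olig1 (15.0-fold) and Olig2 (12.9-fold). This list passed Fisher's exact test when any 1 wt replicate was left out (adjusted exact p from 3.9e-04 to 0.040). Its odds ratio was then 3.54 without wt replicate 1, 7.16 without wt replicate 2 and 10.84 without wt replicate 3. Axon guidance passed without wt replicate 2 (odds ratio 3.34, adjusted exact p = 0.026) or wt replicate 3 (4.17, 0.019). Axon guidance moved with the settings, from an odds ratio of 14.2 with no distance limit to 1.01 against the genes that any list names, and 10 bound genes were fewer than the 11.4 of random lists matched on gene length. Interneuron genes had 5 of 21 (1.56, Fisher's exact test, adjusted exact p = 0.52), with Nr2f1 at 6.10-fold. Their odds ratio was 3.001 without wt replicate 3 (adjusted exact p = 0.15). Sox6 and Gsx2, named after their values were seen, were also bound.

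Lists of other tissues and cell types were not past the threshold. Lymphoid genes known as E2A targets in B and T cells had 2 of 20 (odds ratio 0.555, Fisher's exact test, adjusted exact p = 0.72), Dntt at 11.97-fold and Notch1 at 10.8-fold. Their odds ratio was 1.32 without wt replicate 2 (adjusted exact p = 0.70) and 1.999 without wt replicate 3 (adjusted exact p = 0.37). Skeletal muscle genes had 3 of 18 (1.00, adjusted exact p = 1.00), mural and fibroblast markers 2 of 14 (0.834, adjusted exact p = 1.00), with Col1a1 at 5.82-fold, endothelial markers 1 of 12 (0.455, adjusted exact p = 0.81) and microglia markers 0 of 13 (adjusted exact p = 0.21). Without wt replicate 3 the odds ratios were 0 for muscle genes, 1.38 for mural and fibroblast markers and 0 for endothelial markers, with none past the threshold. Ribosomal protein genes had 4 of 32 (0.714, Fisher's exact test, adjusted exact p = 0.78). Named after their values were seen, the remaining bound genes were Mef2a, Tnnt1 and Myh3 for muscle, Prrx1 for mural and fibroblast markers, Erg for endothelium, and Rpl4, Rpl7, Rpl10a and Rpl27. Housekeeping genes passed with 7 of 18 (3.19, adjusted exact p = 0.042), with Ywhaz at 9.38-fold and the promoter of Polr2a at 9.22-fold. That call ended without wt replicate 2 (2.38, Fisher's exact test, adjusted exact p = 0.25) or wt replicate 3 (3.602, adjusted exact p = 0.13). Without wt replicate 3 it ended with an odds ratio no lower than before, at 4263 consensus regions in place of 12322. Genes are not replicates, and against the narrower background of genes that any list names, 3 of the 22 lists passed in place of 11, a count that was 7 without wt replicate 3.

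**Figure D2:**
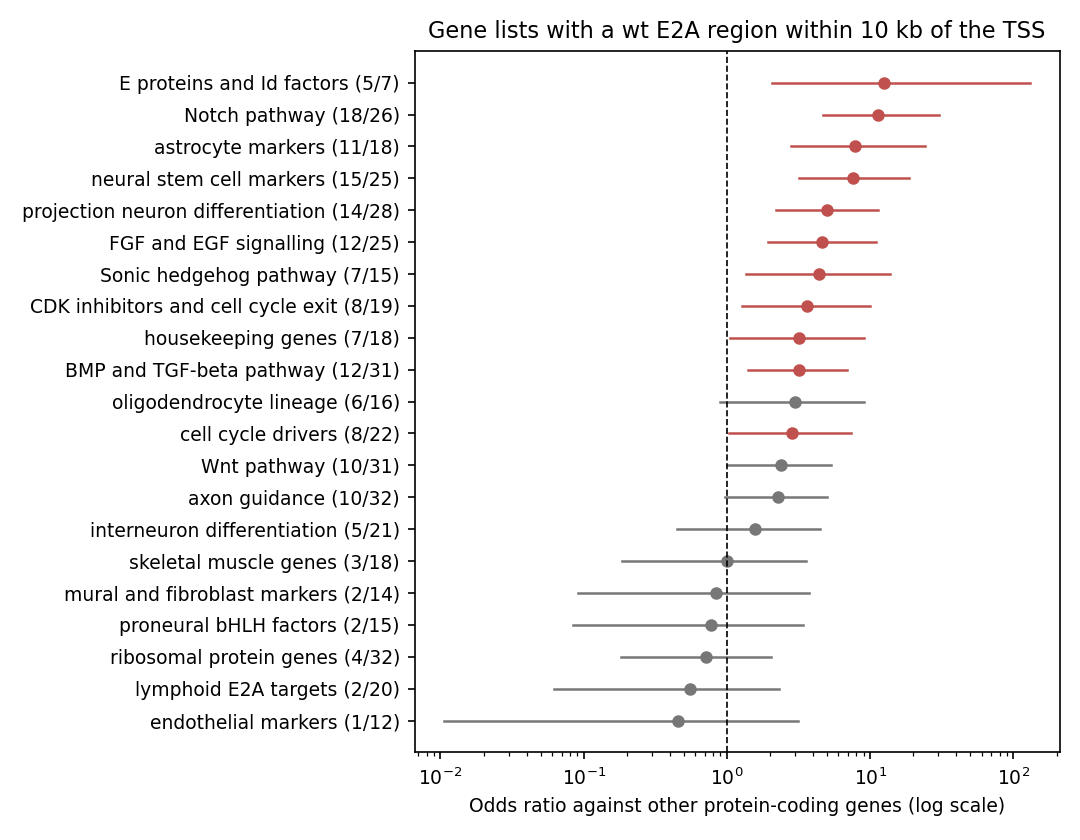
Odds ratio (log-scaled x axis) with its 95% interval for each gene list, against all other protein-coding genes, for having a wt consensus region within 10 kb of the start site; the number of bound genes and list size stand beside each name. Red marks the 11 lists past an adjusted p of 0.05, all above 1, grey the others, and microglia markers, at 0 of 13, are not drawn.

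The knockouts address which splice form a binding site needs, and nearly all wt consensus regions still carried a peak in cells labelled as lacking either form. Of the 12322 regions, 96.6% had a peak in E12KO (95% Wilson interval 96.3 to 96.9, counting error only) and 93.5% in E47KO (93.1 to 93.9). A peak was present in both knockouts at 92.0%, missing in E12KO alone at 184 regions, in E47KO alone at 571 and in both at 230. These counts fell when a wt replicate was left out, but so did the total, since a region then had to be in both remaining lists. They were 106, 354 and 89 of 11013 regions without wt replicate 1, 86, 267 and 138 of 5491 without wt replicate 2, and 12, 72 and 17 of 4263 without wt replicate 3. Without wt replicate 2 the shares present were lower than among all 12322 regions, 95.92% in E12KO and 92.62% in E47KO. Without either other replicate they were higher. The excess of E47KO alone over E12KO alone shrank, to 720 regions against 690 with peak centres within 200 bp, where both counts rose, and to 476 against 411 with E12KO trimmed to the length of E47KO. The order turned, with 495 for E47KO alone against 734 for E12KO alone, with all lists of equal length by width. The labels say only that the antibody is against E2A, so a peak in one knockout can come from the other splice form. By gene, 96.4% of the 3649 protein-coding genes with a wt consensus region within 10 kb had a peak within 10 kb in E12KO, 94.3% in E47KO and 68 genes in neither.

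Among the fixed lists, 162 entries had a wt consensus region within 10 kb. In E12KO 161 of them had a peak within 10 kb, Numb being the exception, and in E47KO 157. Those without one in E47KO included Chrd, the FGF receptor-like gene Fgfrl1, the receptor gene Erbb3 and the embryonic myosin gene Myh3. Except for Chrd, these genes were named after their values were seen. No list member was missing from both knockouts. In each knockout the 11 lists that passed in wt stood high among 10000 random gene lists of the same size, at the 99.1st percentile or above in E12KO and at the 97.03rd or above in E47KO, with lowest values of 84.5, 93.5 and 98.7 in wt replicates 1, 2 and 3. This largely follows from their choice by wt targets, of which 96.4% had a peak in E12KO and 94.3% in E47KO. The random lists were not matched on gene length. Axon guidance and Wnt genes, which did not pass in wt, stood at 99.995 and 99.98 in E12KO and at 98.465 and 99.565 in E47KO, and the other lists that did not pass stood lower than the 11.

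The wt lists put these shares in context. Regions here were merged over all 3 wt lists, so their counts differ slightly from those with a replicate left out (4275 against 4263 for wt replicates 1 and 2). Of 11012 regions shared by wt replicates 2 and 3, 38.4% were in wt replicate 1, against 98.2% in E12KO and 96.0% in E47KO. Of 5491 shared by wt replicates 1 and 3, 77.0% were in wt replicate 2, against 95.9% and 92.6%. Of 4275 shared by wt replicates 1 and 2, 98.9% (98.5 to 99.2) were in wt replicate 3, which is about as long as the knockout lists, against 99.3% (99.03 to 99.5) in E12KO and 97.9% (97.5 to 98.3) in E47KO. Wt replicates 1 and 2 are much shorter than the knockout lists, so only wt replicate 3 gives a comparison at similar length, with 47 regions missing against 29 in E12KO and 88 in E47KO. When every list was trimmed to the same length by peak width, E47KO held the larger share (72.6% against 68.3% in E12KO), so the order of the knockouts changed with that trimming.

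**Figure D3:**
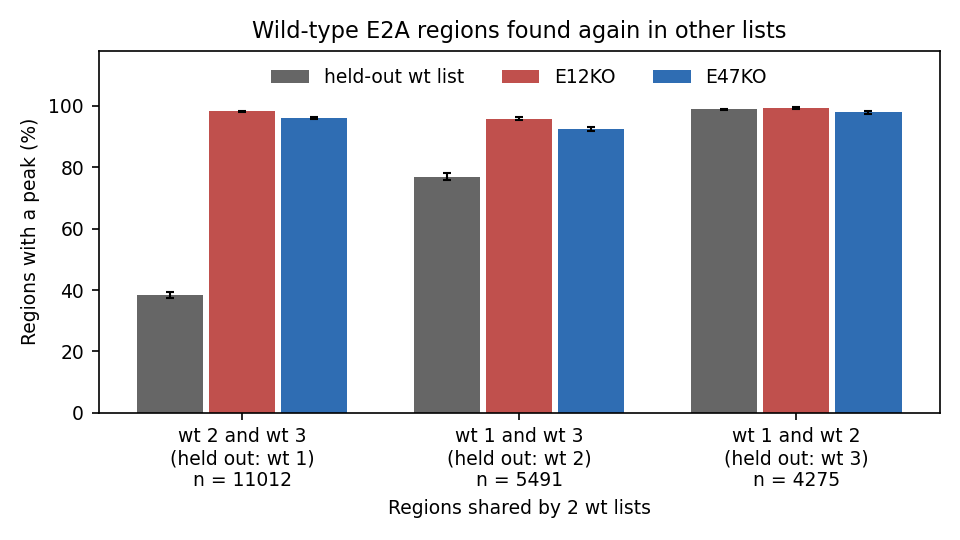
Share of regions common to 2 wt lists that had a peak in the held-out wt list (grey), in E12KO (red) and in E47KO (blue), in percent, with 95% Wilson intervals. Both knockouts lie above the held-out list for wt replicates 1 (38.4%) and 2 (77.0%), and all 3 bars lie between 97.9% and 99.3% where wt replicate 3 was held out.

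Of the 4228 regions in all 3 wt lists, 10 were missing in E12KO only, 60 in E47KO only and 7 in both. The 10 missing in E12KO and present in E47KO were led by a site on chromosome 10 (21643244 to 21643742) in intron 1 of the kinase gene Sgk1, at 12.6-fold and the 77.0th percentile of wt replicate 1 by score. The rest were annotated to Afap1 (9.26-fold), Zfp608 (8.05-fold), Ndp, Rab23, the axon guidance gene Sema5b, Nuak1, Trit1, and the promoters of Gab1 and Ints6. The strongest of the 60 missing in E47KO and present in E12KO reached higher in the ranking, which the larger set alone can give. They were Dscaml1, an adhesion gene, in intron 5 (chromosome 9, 45295365 to 45295892) at 23.1-fold and the 93.1st percentile, the promoter of the synaptic adhesion gene Nrxn2 (chromosome 19, 6497216 to 6497883) at 20.6-fold, a site in intron 2 of Arhgap35 nearest to Npas1 at 18.9-fold and the promoter of Klhl17 at 18.5-fold. Next came Mir674, LOC668415, Parvb, Psmd14, the promoter of the LIM-domain gene Lmo4 (13.2-fold) and Etv1 (9.52-fold, 518054 bp from its start site). The median percentile by score was 35.2 for the 10 regions and 32.1 for the 60, against 61.2 for the 7 missing in both and 61.4 for all 4228.

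The 7 regions missing in both knockouts were annotated to Arhgap5 (11.04-fold), Hopx (10.7-fold, chromosome 5, 77585947 to 77586493, 42345 bp upstream of this stem cell marker), Sycp2 (9.15-fold, in intron 8 of Phactr3), Med13l, Lrrc8d, Lingo1 and the promoter of Lcorl. Independent loss in the 2 knockouts would give 0.269 such regions. Joint loss was compared with that of a wt list and a knockout. Of the regions shared by wt replicates 1 and 2, 17 were missing in both knockouts (0.597 if independent), 12 in wt replicate 3 and E12KO (0.319) and 21 in wt replicate 3 and E47KO (0.967). Of the regions shared by wt replicates 2 and 3, 89 were missing in both knockouts (7.83 if independent), against 178 in wt replicate 1 and E12KO (120.1) and 375 in wt replicate 1 and E47KO (272). Of those shared by wt replicates 1 and 3, 138 were missing in both knockouts (16.5), against 207 in wt replicate 2 and E12KO (51.5) and 338 in wt replicate 2 and E47KO (93.2). The short wt lists limit how far joint loss can exceed independence. Wt replicate 1 lacked 6784 of 11012 regions, and its joint loss could not pass the 195 missing in E12KO or the 442 missing in E47KO. Only wt replicate 3 compares at similar length, and there the knockout pair lay between the pairs that include it.

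Stronger wt peaks were found again more often in every other list. From the weakest to the strongest of 5 equal bins of wt replicate 1 peaks, the share with a peak in E12KO was 72.6%, 78.7%, 83.8%, 88.2% and 92.4%, and in E47KO 67.1%, 73.7%, 79.4%, 85.5% and 90.5%. The wt lists followed the same course, from 70.6% to 92.2% in wt replicate 3 and from 44.5% to 85.5% in wt replicate 2. In each bin E47KO lay below E12KO and wt replicate 3 and above wt replicate 2. The order of the knockouts turned in the strongest bin with lists of equal length by width (61.9% in E47KO against 57.4% in E12KO) and in the weakest with peak centres within 200 bp (46.5% against 46.2%). Some peaks had no counterpart at any strength: 21.1% of the weakest bin and 5.94% of the strongest were in none of the other 4 lists.

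**Figure D4:**
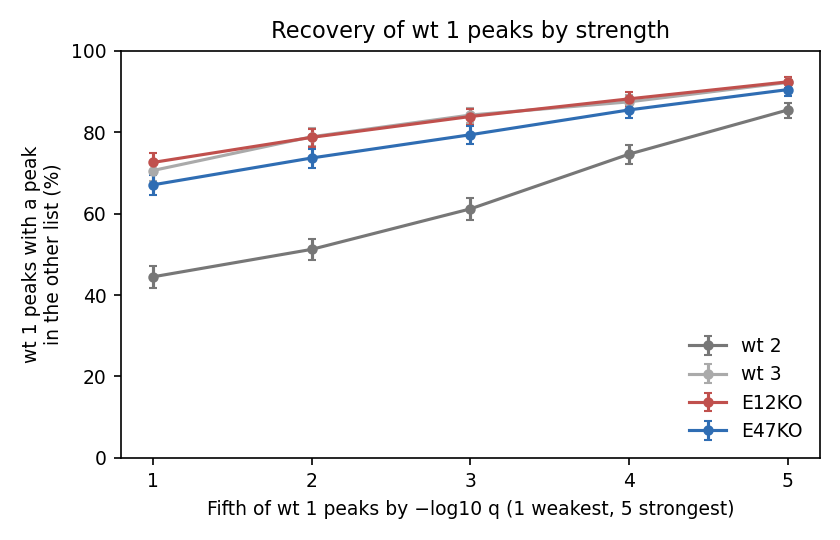
Percent of wt replicate 1 peaks with a peak in another list (y axis), in 5 equal bins of the authors' −log10 q (x axis, 1 weakest, 5 strongest), with 95% Wilson intervals. All 4 lists climb with strength, from between 44.5% and 72.6% in bin 1 to between 85.5% and 92.4% in bin 5.

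In the reverse direction, 1441 regions had a peak in both knockouts and in no wt list. Ranked by peak width, because the knockout lists carry no score, the 10 highest were mostly promoters: Zfp787 (chromosome 7, 6106427 to 6108285), Ninj1, Mdga1, Peli2, the FGF receptor gene Fgfr1 (chromosome 8, 26629219 to 26631484), the m6A reader gene Ythdf2, Tst and Hnrnpll, with intergenic regions nearest to Nemp2 and Zfp692. Promoters made up 35.7% of these peaks in E12KO against 27.0% of its other peaks, and 35.6% in E47KO against 24.6%. Peaks found in E12KO alone had a similar promoter share (35.4% against 26.4% of its other peaks), while those in E47KO alone did not (24.6% against 25.4%). The count rested on wt replicate 3, without which it was 7266.

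By count, most E2A peaks lay outside promoters. The share of the genome in each feature class was not measured, so these shares show neither enrichment at promoters nor avoidance of them. Over the 3 wt lists 21.2% ± 3.24 (SD, n = 3) of peaks were within 1 kb of a start site, 35.4% ± 0.985 in introns, 36.0% ± 2.37 in distal intergenic sequence and 2.83% ± 0.418 in exons. In E12KO 27.5% of peaks were at promoters and 32.7% in introns, and in E47KO 25.3% and 34.3%. The E12KO promoter share lay above the highest wt value, 24.9% in wt replicate 3, by less than the spread among the wt lists, and E47KO, at 25.3%, was close to that wt list. With every list trimmed to its widest 6814 peaks, which changes both length and the kind of peak, promoter shares were 26.8% over wt, 44.8% in E12KO and 37.6% in E47KO. The list of wt replicate 1 already had that length, so it was left unchanged and entered the wt mean at 19.1%. That mean is therefore not a like comparison for the trimmed knockout lists.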

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

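The test of this part was chosen after the values were seen. The summit file of wt replicate 1 holds 1 position on the mitochondrial genome, at 15591, with a −log10 q of 28.1, which stands outside the comparisons because the annotated table of the same library leaves it out. Its 6815 summits otherwise match the 6814 annotated peaks one for one. No control library was analysed here, so the level of this signal without antibody is not known.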

How the results depend on the processing

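The tests that used peak width, peak centres for the strength bins, or a background of genes that any list names were chosen after the data were seen. Depth is unknown for every list, and 4 of the 5 lists have no score, so alternatives that rank all lists by score (the same number of peaks, the stricter 0.5 of each list, the same minimum score) and the E-box motif counts were not run. Width only partly follows score, which limits the width-based values. No gene list past the threshold changed its direction, but the order of the knockouts did: E12KO held 3.14 percentage points more of the wt consensus regions than E47KO, 0.266 more with peak centres within 200 bp, and −4.31 with lists of equal length by width.

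With regions in all 3 wt lists there were 4228 regions, of which 99.60% were in E12KO and 98.42% in E47KO, with 10 missing in E12KO only, 60 in E47KO only and 7 in both, and 7 gene lists passed; with regions in any wt list there were 26817, with shares of 77.79% and 70.75% and 1323, 3213 and 4632 missing. Both follow from the number of lists required. Leaving out each wt replicate gave 4263 to 11013 consensus regions, shares of 95.92% to 99.32% in E12KO and 92.62% to 97.91% in E47KO, 12 to 106 regions missing in E12KO only, 72 to 354 in E47KO only, 17 to 138 in both, 1539 to 7266 in both knockouts and no wt list, and 7 to 11 gene lists past the threshold. Allowing 1 wt list to hold them gave 7558 regions in both knockouts.

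Matching peak centres within 200 bp lowered the shares to 88.68% in E12KO and 88.42% in E47KO and raised the regions missing in E12KO only to 690 and in both to 586. It put the share of wt replicate 1 peaks found in E12KO at 46.22% in the weakest bin and 69.99% in the strongest, and in E47KO at 46.52% and 69.55%; the cause was not tested. Lists of equal length by width gave 5542 consensus regions, of which 68.31% were in E12KO and 72.63% in E47KO, with 734 missing in E12KO only, 1022 in both, and 384 regions in both knockouts and no wt list. Promoter shares in these lists were 26.80% over wt, a mean that includes the unshortened list of wt replicate 1, 44.80% in E12KO and 37.63% in E47KO. The weakest and strongest bins were found at 39.77% and 57.45% in E12KO and 38.30% and 61.85% in E47KO. The cause was not tested. The wider 0.5 of each list gave 6108 consensus regions, shares of 91.08% and 88.87%, and 815 regions in both knockouts and no wt list, from fewer peaks. Trimming E12KO to the length of E47KO lowered its share to 94.03% and raised the regions missing in it alone to 411.

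Of the 22 gene lists, 3 passed against genes that any list names and 3 against random lists matched on gene length, the same 3 in each: the Notch pathway (18 bound genes against 7.69 in matched lists, adjusted exact p = 8.3e-04), neural stem cell markers (15 against 7.58, 0.038) and astrocyte markers (11 against 5.19, 0.045). These 3 also passed in the other 8 alternatives. E proteins and Id factors and projection neuron genes passed in 8 of 10 alternatives, FGF and EGF signalling in 6, CDK inhibitors and BMP and TGF-β in 5, cell cycle drivers in 4, Sonic hedgehog in 3 and housekeeping genes in 2. Oligodendrocyte and axon guidance genes passed in 6 alternatives and Wnt genes in 2, while microglia markers, with 0 bound genes, passed in 1 as less often bound. Over all lists and alternatives 166 calls stayed on their side of the threshold, 39 were lost and 15 gained.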

Other observations

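All tests of explanations in this part were chosen after the result was seen. Peaks per gene were counted at any distance from the start site, without the 10 kb limit used for target genes and without adjustment for the size of the gene or its surroundings. The zinc-finger gene Zfp608, which was singled out with the genes named here after the values were seen, had the most annotated peaks of any gene by wt mean. It had 21, 31 and 43 in wt replicates 1 to 3 (mean 31.7 ± 11.02, SD, n = 3), 48 in E12KO and 41 in E47KO. The adhesion gene Ntm had 10, 16, 29, 23 and 24 in the same order. Tcf4, which encodes the E protein E2-2, had 6, 15, 21, 24 and 23, of which 1, 3, 4, 6 and 5 lay within 10 kb of its start site. The widest peak of wt replicates 2 and 3, E12KO and E47KO lay on chromosome 4 and was annotated to Ttc34 in each, at 12356, 12587, 12513 and 12622 bp, while the widest in wt replicate 1 was 2207 bp. The only peaks on the Y chromosome were 3 in E47KO.

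Strong wt replicate 1 peaks were not always found elsewhere: 81 of the 1363 in its strongest bin, 5.94% (95% Wilson interval 4.81 to 7.33), were in none of the other 4 lists. Of these 81, 35 (43.21%) had a local background (pileup over fold enrichment) above the 99th percentile of the strong peaks found elsewhere, with 15 on chromosome 6 and 13 on chromosome 9, so high-copy repeats that were handled differently in the other lists may account for that part. One cluster lay at 47603420 to 47727105 on chromosome 6, with 37 peaks in wt replicate 1 and 1 in each other list, and another at the start of chromosome 9, with 24 against 0. The other 46, such as a peak at the promoter of Zfp369 (chromosome 13, 65379550 to 65380207, 29.1-fold), had a median local background of 2.80, against 3.22 for strong peaks found elsewhere, and their source stays open. These peaks set 1 wt library against wt and knockout libraries alike, so no biological explanation was tested.

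E47KO lacked more wt consensus regions than E12KO, 801 against 414. With E12KO shortened to the length of the E47KO list by width, the difference fell from 387 to 65 regions. Removing peaks from E12KO can only add regions missing in it, so the difference could not grow. How far it fell depends on the use of width, which in E12KO correlated with the wt replicate 1 score at only 0.105. How much of the difference comes from list length therefore cannot be told from this comparison. Binding that needs E47 stays open: 1 of the 3 held-out wt lists, wt replicate 3, missed fewer regions than E47KO (47 against 88), and the others are too short to compare. With 1 library per knockout, an effect of genotype and a difference between libraries, including one in list length, cannot be told apart.

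The 1441 regions in both knockouts and no wt list held narrow peaks, at a median width percentile of 32.92 in E12KO and 27.8 in E47KO, so narrow peaks near the calling threshold may make up part of this set. Width followed score only weakly, however, and peaks found in wt replicate 3, E12KO or E47KO alone were narrower still, at percentiles 15.2, 22.2 and 14.6. For binding gained in both knockouts, 3 lists were compared at equal length by width: the knockouts shared 1679 regions absent from wt replicate 3, while wt replicate 3 shared 2004 with E12KO that E47KO lacked and 1625 with E47KO that E12KO lacked. The knockout pair thus lay between the pairs that include a wt list, and with 1 library per knockout gained binding and a difference between libraries cannot be told apart.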
